A study of Mus musculus with 7 samples.

How the data were processed

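RNA of cultured mouse haematopoietic stem cells was sequenced in 7 libraries: 3 of cells given the solvent DMSO, 2 of cells given gemcitabine at 0.5 µM (Gem) and 2 of cells given hydroxyurea at 100 µM (HU), all after 48 h. Per the labels' protocols, the cells were sorted from the bone marrow of C57BL/6J mice, RNA was taken up with a miRNeasy kit, complementary DNA was amplified with a Geo-seq protocol for small inputs, and libraries were made with a transposase kit (TruePrep). The labels' protocols do not say that the reads carry strand, so a gene and its antisense partner are not told apart here.

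The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) for 52224 genes and the 7 libraries, written to 2 decimals. Every column named a library of the labels, 0 columns were left unused, and 0 lines lacked a gene name. The submitters' processing notes name Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq, DESeq2 and the genome build mm10, with no role or order. Which tool made the FPKM values and which gene annotation was used are not given in the sources used here. The values were used as deposited. FPKM divides by transcript length and by the mapped fragments of a library, and short genes are estimated poorly. If all mapped fragments were counted, which is not given, fragments from elsewhere in the genome lower the value of all genes.

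Depth could not be read from the values. In a search for the step of 1 read among low values, 29.5% to 35.0% of values per library lay within 0.1 of a whole number of steps. A step fixed in advance gives 20% by chance, but the step was fitted to the same values, so chance lies higher. No reads were recovered, and the depth is unknown. No intervals that need a depth are given.

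Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3; figures were drawn in Python 3.11.15. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 13865 in all. One model held the 3 groups, with a moderated variance and a mean-variance trend, 4 residual degrees of freedom and no block. Contrasts were Gem against DMSO, HU against DMSO and Gem against HU. A separate model set the 4 drug libraries against the 3 DMSO libraries. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p below 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Unless another tool is named, adjusted p-values of genes are limma's with Benjamini-Hochberg adjustment.

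Gene groups were tested with limma's camera at a preset correlation of 0.01 over 30 lists, adjusted by Benjamini-Hochberg over the lists. A list's relative median is its median log2 fold change minus that of all genes tested. Camera was repeated with a correlation estimated per list, and fry was run as another list test. Counts of list members that passed are given over all genes tested and adjusted over the list alone.

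The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. In each drug against DMSO the rule took Dek, Cdkn1a, Mdm2, Rrm2 and Mki67. It added the 6 largest rises and 6 largest falls at an adjusted p below 0.05 with a mean FPKM of at least 5, no overlap between drug and DMSO libraries, and a symbol that is not a predicted or clone name. It also took up to 3 members with the smallest p from each list that passed. Of the genes the rule took, 2 are not reported here. For Gem against HU it took 4 genes each way, filled by the smallest p where fewer passed. Other genes named were chosen after their values were seen, and this is said where they appear.

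Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling each library to the same sum (TPM scale), quantile normalization, trimmed-mean scaling, no mean-variance trend, library weights, leaving out each library in turn, a block for the replicate number, models with only the compared groups, and the mean of the drug contrasts. Trimmed-mean scaling was computed on FPKM after removing 30% of genes at each end of the ratios and 5% at each end of the levels; values after it are called scaled. A length correction, a length and level correction (loess with a span of 0.3 on genes outside the lists) and the scaling of the list tests were added after the data were seen. Lengths are exonic lengths in GENCODE M21, which also gave the coordinates (GRCm38, the assembly of mm10); 96.8% of the tested genes had one. For the list of replication-dependent histones the length check is void, since no member matched by symbol.

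Background was measured on 1998 olfactory and vomeronasal receptor genes, a set chosen after the data were seen. A background share of the fragments was estimated from their mean FPKM over the 2.72 Gb that the annotation spans. This takes FPKM as divided by all mapped fragments, which is not given.

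The gene and list steps were tested on simulated data drawn from the real means and spreads of the 13865 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. The gene step found 67% and 88% of these for Gem against DMSO, 60% and 90% for HU against DMSO, 61% and 92% for Gem against HU and 86% and 95% for both drugs pooled, with 7, 9, 8 and 8 false calls. A list shifted by -0.3 was found in each comparison of single groups, with 0 of 29 other lists called. The draws used means and spreads of genes, so this does not speak for lists whose members vary together. Ribosomal protein genes did so in the real data, at an estimated correlation of 0.762. Comparisons that share the DMSO libraries were set beside 20 simulations of unchanged groups against the same libraries.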

Results

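Gene expression was measured in haematopoietic stem cells, the rare bone marrow cells that renew the blood, after 48 h in culture with a drug that disturbs DNA replication. The cells came from wild-type C57BL/6J mice and were sorted as lineage-negative cells that carried Sca-1, c-Kit and CD150 but no CD48. They were given DMSO as the solvent control (n = 3 libraries), gemcitabine at 0.5 µM (Gem, n = 2) or hydroxyurea at 100 µM (HU, n = 2). Gemcitabine is a cytidine analogue that is built into DNA, and hydroxyurea inhibits ribonucleotide reductase, the enzyme that makes deoxynucleotides. The series title names the chromatin protein DEK, tolerance of replication stress and Fanconi anaemia. The comparisons address which transcripts differ between these cells with and without either drug. Values are FPKM as deposited for 52224 genes, of which 13865 were tested, and the sequencing depth is unknown. The labels do not say that the libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

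The cultured cells held abundant myeloid transcripts. Ftl1 and Fth1, which encode ferritin chains, and Lyz2, the myeloid lysozyme, were the 3 genes with the highest mean FPKM in DMSO, at 37476 ± 5614, 17185 ± 3409 and 25887 ± 4563 (SD, n = 3). Their lowest values in the 4 drug libraries, 50162, 21694 and 32469, lay above their highest in DMSO, 43602, 21010 and 30761. In limma 0 of the 3 passed in either drug as deposited (adjusted p from 0.0797 for Ftl1 in HU to 0.139 for Lyz2 in Gem). After scaling Ftl1 and Lyz2 passed in HU (0.0363 and 0.0495). The neutrophil granule genes Mpo and Elane stood at 3234 ± 627 and 1858 ± 622 FPKM, S100a8 at 4292 ± 1128, and the platelet chemokine gene Pf4 at 2124 ± 516. Of the surface markers used in the sort, Cd48, whose protein was absent from the sorted cells, reached 213 ± 10.9 FPKM, while Slamf1, the gene of CD150, was at 0.930 ± 0.454 and Ly6a, the gene of Sca-1, at 39.2 ± 7.91. Of stem cell genes Mecom, Hlf and Fgd5 were at 0.323 ± 0.136, 2.24 ± 1.26 and 0.0233 ± 0.0252 FPKM, and Procr, Hoxa9 and Gata2 at 14.0 ± 3.54, 9.31 ± 0.481 and 24.8 ± 8.44, against 123 ± 5.71 for Cd34 and 43.9 ± 4.05 for Kit. These genes were chosen after the data were seen, and no cells before culture were analysed here.

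The drug libraries differed from the DMSO libraries over the whole table. The FPKM of all genes summed to 818775 to 832979 in DMSO, 703016 to 729258 in Gem and 647760 to 651315 in HU. Between 21251 and 23047 genes were above 0 in DMSO, 27887 to 29158 in Gem and 29687 to 31153 in HU. Olfactory and vomeronasal receptor genes, which are not known to serve blood cells, were above 0 for 395 ± 12.1 of 1998 genes in DMSO, 1043 ± 57.3 in Gem and 1258 ± 24.0 in HU. Over the 4 drug and 3 DMSO libraries each of these measures gave an exact two-sided permutation p = 0.0286, the smallest that the 35 splits allow. The 10 most abundant genes held 18.0% ± 2.21 of the FPKM in DMSO, 24.6% ± 0.895 in Gem and 25.8% ± 0.339 in HU. The median gene changed by -0.25 (log2) in Gem and -0.30 in HU, and by 0.0093 and 0.013 after trimmed-mean scaling, so changes are given as deposited and relative to this shift. Pearson correlations between libraries, across tested genes on the log scale (genes are not independent replicates), were 0.965 to 0.981 within groups and 0.950 to 0.969 between groups. DMSO 3 stood apart from DMSO 1 and DMSO 2 in inflammatory genes chosen after the data were seen: Il1a was at 21.38 FPKM against 4.67 and 3.53, Cxcl1 at 16.69 against 0.32 and 0.07 and Ptgs2 at 9.67 against 0.65 and 0.22. It also lay towards the drug libraries for Jun (21.79 against 15.93 and 16.25), Nfkb2 (32.04 against 19.14 and 20.95) and Lars2 (62.42 against 47.23 and 52.77), and in the relative medians of oxidative phosphorylation (-0.089 against 0.047 and 0.025) and ribosomal protein genes (-0.15 against 0.038 and 0.13). Without DMSO 3 the counts given below were 3367 genes in Gem and 5192 in HU, with 12 and 13 lists.

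**Figure D1:**
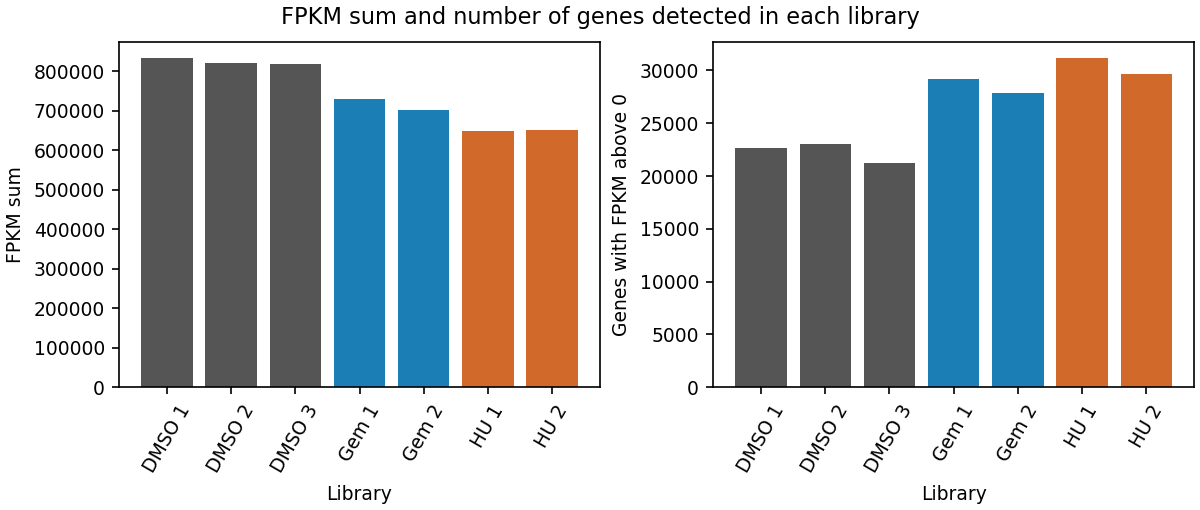
Bars start at 0 and show, for each of the 7 libraries, the FPKM summed over all genes and the number of genes above 0, on 2 separate axes. The 4 drug libraries have lower sums (at most 729258) and more genes above 0 (at least 27887) than the 3 DMSO libraries.

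In Gem against DMSO, which asks what gemcitabine changed, the largest rises among named genes detected in DMSO were those of transcription factors of the early stress response. Jun and Fos, which together form AP-1, were at 18.0 ± 3.29 and 27.9 ± 1.72 FPKM in DMSO (SD, n = 3) and at 148 ± 6.36 and 128 ± 8.29 in Gem (n = 2). Their log2 fold changes were 2.98 ± 0.14 (SE, limma, Benjamini-Hochberg adjusted p = 2.22e-04) and 2.15 ± 0.08 (adjusted p = 8.83e-05). Nfkb2, a subunit of NF-kB, rose from 24.0 ± 6.98 to 117 ± 3.23 FPKM, and Egr1, a zinc finger factor, from 2.27 ± 0.311 to 11.0 ± 2.68 (limma adjusted p = 0.00545 for each). Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 54.1 ± 7.69 to 131 ± 7.16 FPKM (limma adjusted p = 0.00545). All 5 stayed past the threshold after scaling, and after scaling their log2 fold changes ran from 1.57 for Lars2 to 3.27 for Jun. The microRNA gene Mir1982 was listed at 0 in the DMSO and HU libraries and at 54.18 and 59.11 FPKM in Gem. Its 74 bases lie within the gene Oaz1 on the same strand, so its reads cannot be told apart from those of Oaz1.

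Genes of chromatin packing and DNA replication were among the falls in Gem. Cbx3, which encodes heterochromatin protein HP1 gamma, fell from 253 ± 49.8 to 59.8 ± 12.4 FPKM, a log2 fold change of -2.06 ± 0.19 (SE, limma adjusted p = 0.00545) and of -1.76 after scaling (adjusted p = 0.0146). Set, a histone chaperone, fell from 218 ± 17.7 to 106 ± 12.2 FPKM and Rpa3, a subunit of the single-strand binding protein RPA, from 65.7 ± 4.91 to 31.8 ± 2.09, with scaled log2 fold changes of -0.74 and -0.73 (limma adjusted p = 0.0227 and 0.0149). Dek was at 141 ± 5.38 FPKM in DMSO and 93.0 ± 2.81 in Gem, a log2 fold change of -0.59 ± 0.07 (SE, limma adjusted p = 0.00574), but -0.29 after scaling (adjusted p = 0.0969). Cdkn1a, the p53 target that encodes p21, was at 99.8 ± 8.09 and 65.4 ± 5.90 FPKM (limma adjusted p = 0.0198, and 0.301 after scaling). As deposited the log2 fold change of Cdkn1a was -0.60. Its call was lost without DMSO 1 (-0.63, limma adjusted p = 0.0531), without DMSO 2 (-0.54, 0.0535), without Gem 1 (-0.51), without Gem 2 (-0.69), with no filter and with no trend. The p53 regulator Mdm2, the reductase subunit Rrm2 and the proliferation marker Mki67 passed neither test, with log2 fold changes of -0.31, -0.32 and -0.35 as deposited and -0.019, -0.025 and -0.080 after scaling. As deposited Rrm2 passed without DMSO 2 (-0.49, limma adjusted p = 0.0262), where it stood at 63.31 FPKM against 87.63 and 92.31 in the other DMSO libraries. Mki67 passed at a mean FPKM of at least 5 (adjusted p = 0.0367) and with library weights (0.0430). Further falls were those of Hba-a2, an alpha globin gene (-1.68, and -1.43 after scaling, adjusted p = 0.0409), of mt-Nd4l, a subunit of complex I (-1.75, but scaled adjusted p = 0.0832), and of the ribosomal protein pseudogenes Rpl15-ps3, Rpl27-ps3 and Rps23-ps1. Those 3 pseudogenes share reads with their parent genes and are uncertain, none passed after scaling, and Rpl15-ps3 was at 10.61 and 0 FPKM in Gem. Cbx3, Set, Npm1 and the neighbours Nme1 and Nme2 also have close copies or joint transcripts, and Jun and Nfkb2 overlap antisense genes, so their values carry the same doubt.

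In the mouse annotation of build GRCm38 (mm10), Jun is a gene of 1 exon on chromosome 4 (95049034 to 95052222, minus strand), Fos lies on chromosome 12 (85473890 to 85477273), Nfkb2 on chromosome 19 (46304320 to 46312385) and Egr1 on chromosome 18 (34859823 to 34864984), all 3 on the plus strand. Dek lies on chromosome 13 (47084775 to 47106201, minus strand), Cbx3 on chromosome 6 (51470360 to 51483704), Set on chromosome 2 (30057378 to 30072577), both on the plus strand, and Mir1982 on chromosome 10 (80828797 to 80828870). FPKM values cover whole genes, so no exon or untranslated region is told apart.

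In Gem, 3421 genes passed, 208 higher and 3213 lower, whereas after scaling 132 passed, 67 higher and 65 lower, of which 126 were called in both. Of the 39 genes that the naming rule took and that passed, 17 also passed after scaling and 10 after a correction for transcript length and level, which was added after the data were seen. The count rested on single libraries: it was 12 genes, all higher, without Gem 2, when of these genes only Jun, Fos and Mir1982 passed, 1417 without Gem 1, 1499 without DMSO 1 and 2115 without DMSO 2.

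**Figure D2:**
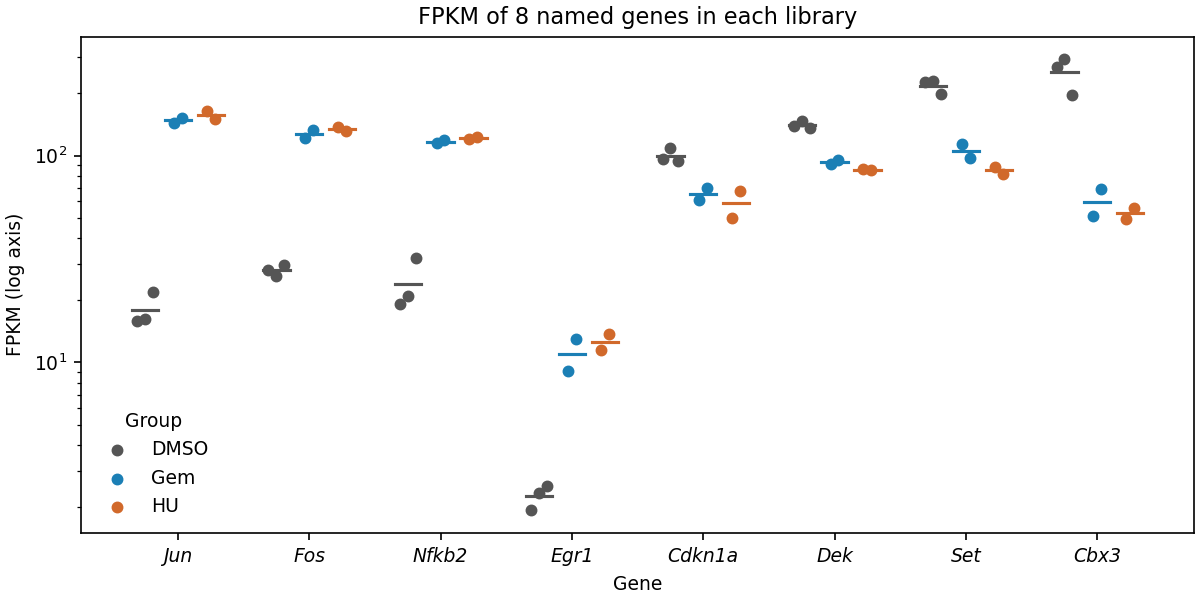
FPKM on a log axis of Jun, Fos, Nfkb2, Egr1, Cdkn1a, Dek, Set and Cbx3, with 1 point per library and a line at the mean of each group (DMSO n = 3, Gem n = 2, HU n = 2). Jun lies between 15.93 and 21.79 FPKM in DMSO and between 143.28 and 164.14 in the drug libraries, while Cdkn1a, Dek, Set and Cbx3 lie lower in the drug libraries as deposited.

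Among the 30 gene lists in Gem, the clearest group as deposited was oxidative phosphorylation, the subunits of the respiratory chain. Of its 48 tested members 43 fell as deposited (44 adjusted over the list alone), and 4 fell after scaling (29 adjusted over the list alone). The median relative to all genes was -0.32 (limma camera, Benjamini-Hochberg adjusted p = 8.24e-13, and adjusted p = 0.634 with an estimated correlation). With the length and level correction it was -0.063 (camera adjusted p = 0.0169). Atp5g1 fell from 507 ± 49.8 to 250.4 ± 29.6 FPKM, Cox5b from 549 ± 48.3 to 310.2 ± 23.7 and Ndufs8 from 236 ± 18.7 to 136 ± 12, all 3 on both scales. Of 80 ribosomal protein genes 44 fell (57 adjusted over the list alone), but 2 after scaling (4 adjusted over the list alone); the relative median was -0.24 (camera adjusted p = 2.85e-07, and 0.731 with an estimated correlation). Rpl29 fell from 570.1 ± 37.1 to 331 ± 21.7 FPKM on both scales, and Rpl7a from 720 ± 68.4 to 418 ± 23.4 as deposited only. The list's relative median was -0.18 and -0.27 in the single Gem libraries and -0.15 in DMSO 3, so that the groups lay close together.

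Lists of chromatin, replication and ribosome assembly genes were also lower in Gem. In the list of DEK and histone chaperones 17 of 24 genes fell (19 adjusted over the list alone), with 2 after scaling (5 adjusted over the list alone), Cbx3 and Set leading. Of 42 DNA replication genes 19 fell (32 adjusted over the list alone), with 2 after scaling (3 adjusted over the list alone); these were Rpa3 and Gmnn, the licensing inhibitor geminin, at 68.3 ± 4.06 and 39.7 ± 1.03 FPKM, while Tipin of the fork protection complex fell as deposited only. Of 35 ribosome biogenesis genes 21 fell (29 adjusted over the list alone), with 0 after scaling (3 adjusted over the list alone), among them Fbl, Npm1 and Gnl3 with log2 fold changes of -0.66, -0.61 and -0.63. Nucleotide metabolism had 19 of 33 lower (22 adjusted over the list alone) and 1 after scaling (2 adjusted over the list alone), led by Dtymk, Nme1 and Nme2. The integrated stress and unfolded protein response had 19 of 35 lower (23 adjusted over the list alone) and 0 after scaling (1 adjusted over the list alone), led by Sdf2l1, Hyou1 and Asns. Relative medians of these 5 lists were -0.20, -0.15, -0.19, -0.16 and -0.12, with camera adjusted p = 1.92e-05, 5.97e-05, 1.10e-05, 0.00183 and 0.00143, and adjusted p = 0.634 for each with an estimated correlation. These 5, oxidative phosphorylation and ribosomal proteins also passed after scaling. With the length and level correction DNA replication, nucleotide metabolism and the integrated stress list lost their call (camera adjusted p = 0.130, 0.217 and 0.626) and the other 4 kept it. The relative medians of those 4 were then smaller in size: -0.063 for oxidative phosphorylation, -0.081 for ribosomal proteins, -0.080 for DEK and histone chaperones and -0.091 for ribosome biogenesis.

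The other 4 of the 11 lists that passed in Gem, 9 lower and 2 higher, lost their call after scaling. Of 46 genes of G2/M and mitosis 18 fell (28 adjusted over the list alone), among them Pttg1, Birc5 and Aurkb with log2 fold changes of -0.68, -0.69 and -0.54 (list camera adjusted p = 0.00183, but 0.0513 after scaling, 0.105 without Gem 2, and 0.692 with an estimated correlation). Of 24 cholesterol synthesis genes 12 fell (16 adjusted over the list alone), with Ebp and Fdps at -0.64 and -0.54 (camera adjusted p = 0.0188, 0.219 after scaling, 0.0915 without DMSO 3, and 0.634 with an estimated correlation). The immediate early list passed as higher (camera adjusted p = 0.0188, 0.142 after scaling, 0.0584 without Gem 2, and 0.634 with an estimated correlation), although its median was -0.14 as deposited and 0.11 relative to all genes. In it 4 of 20 genes rose and 5 fell (4 and 6 adjusted over the list alone), and after scaling 3 rose, Jun, Fos and Egr1. The stromal and endothelial markers passed as higher (camera adjusted p = 0.0431, 0.304 after scaling, and 0.634 with an estimated correlation) with 0 of 6 genes past limma's threshold and 0 adjusted over the list alone. Sparc was at 4.82 FPKM in Gem 1 and at most 1.12 in the other libraries, Cxcl12 and Spp1 had log2 fold changes of 0.28 and -0.25, and the list's adjusted p was 0.600 without Gem 1, 0.167 without DMSO 2, 0.0915 without DMSO 3, 0.0542 without HU 1 and 0.0545 without HU 2.

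The 19 lists that did not pass in Gem had camera adjusted p from 0.151 to 0.999. Their member counts stand beside 3213 of all 13865 genes tested that fell as deposited. Of 34 p53 targets 0 rose and 7 fell (7 adjusted over the list alone; relative median -0.062, adjusted p = 0.406). Of 26 genes of the Fanconi anaemia pathway, which repairs cross-linked DNA, 0 rose and 2 fell (1 adjusted over the list alone; -0.017, adjusted p = 0.725), and of 30 replication checkpoint genes 0 rose and 8 fell (9 adjusted over the list alone; 0.015, adjusted p = 0.725). The stem cell identity list had 10 of 37 lower (11 adjusted over the list alone, adjusted p = 0.406). Camera adjusted p was 0.208 for G1/S cyclins and for apoptosis regulators, 0.576 for end joining and recombination, 0.151 for glycolysis, 0.810 for the oxidative stress response and 0.800 for inflammatory and NF-kB genes. It was 0.557 for granulocyte and monocyte, 0.406 for erythroid, 0.406 for megakaryocyte and platelet, 0.725 for mast cell and basophil and 0.414 for lymphoid markers, 0.406 for the interferon response, 0.999 for mitochondrially encoded genes and 0.800 for replication-dependent histones. Lysosome and autophagy did not pass as deposited (adjusted p = 0.406) but passed as higher after scaling (adjusted p = 0.0121, median 0.13, 0 of 35 genes past limma's threshold) and with the length and level correction (0.16, adjusted p = 1.34e-05). The oxidative stress response also passed as higher with that correction (0.081, adjusted p = 0.0169). The test, median and mean differed in sign for the replication checkpoint, lysosome, oxidative stress and histone lists. With an estimated correlation 0 lists passed in camera, 1 at an unadjusted p under 0.05, while fry called 23.

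HU against DMSO asks the same of hydroxyurea, and its named rises were largely those of Gem. Jun stood at 157 ± 10.3 FPKM in HU (SD, n = 2), Fos at 135 ± 3.90, Nfkb2 at 121 ± 1.85 and Egr1 at 12.6 ± 1.57. Their log2 fold changes against DMSO were 3.07 ± 0.14, 2.24 ± 0.08, 2.33 ± 0.19 and 2.06 ± 0.18 (SE), with limma adjusted p = 2.71e-04, 1.35e-04, 0.00102 and 0.00102, and all 4 passed after scaling. The mitochondrial tRNA gene mt-Tq, which overlaps mt-Ti, was listed at 0 in all 3 DMSO libraries and Gem 1, at 6334.67 FPKM in Gem 2 and at 6827.01 and 5970.22 in HU; its limma adjusted p was 0.0141, but 0.0997 without HU 1 and 0.0880 without HU 2. The ribosomal RNA copy n-R5s88, at 0, 14.39 and 0 FPKM in DMSO and 36.17 and 22.30 in HU, passed as deposited (limma adjusted p = 0.0406) but not after scaling (0.0716), nor without DMSO 1 (0.106), DMSO 3 (0.0913), Gem 1 (0.0695), Gem 2 (0.0696), HU 1 (0.214) or HU 2 (0.137).

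Chromatin and replication genes fell in HU as well. Cbx3 fell to 52.5 ± 4.66 FPKM, Set to 84.9 ± 4.53, Rpa3 to 26.6 ± 0.318 and Orc6, a subunit of the origin recognition complex, from 40.2 ± 3.06 to 18.3 ± 0.170. Their log2 fold changes after scaling were -1.87, -0.99, -0.91 and -0.74 (limma adjusted p = 0.00441, 0.00358, 0.00313 and 0.00953). Dek fell to 85.6 ± 1.06 FPKM, a log2 fold change of -0.71 ± 0.07 (SE, limma adjusted p = 0.00102) and of -0.35 after scaling (adjusted p = 0.0222). Cdkn1a was at 58.7 ± 12.2 FPKM (log2 -0.77, limma adjusted p = 0.00497, but 0.0992 after scaling). Mdm2, Rrm2 and Mki67 did not pass, at -0.18, -0.34 and -0.26 as deposited and with the opposite sign, 0.17, 0.016 and 0.073, after scaling. Rrm2, whose protein is the target of hydroxyurea, passed as deposited without DMSO 2 (-0.51, limma adjusted p = 0.0102). Nme1, a nucleoside diphosphate kinase, fell from 147 ± 13.7 to 44.6 ± 0.827 FPKM, a scaled log2 fold change of -1.34 (limma adjusted p = 0.00249). Fcer1a, the IgE receptor chain of mast cells and basophils, fell from 61.4 ± 38.6 to 11.1 ± 1.41 FPKM (scaled -1.84, limma adjusted p = 0.0385), but as deposited its adjusted p was 0.0582 without HU 1 and 0.0684 without HU 2. The spliceosomal RNA gene Rnu4atac was listed at 0 in HU and at 8.19, 11.11 and 51.22 FPKM in DMSO. The pseudogenes Rpl15-ps3, Rpl27-ps3 and Rpl38-ps2 also fell, of which Rpl27-ps3 passed after scaling (limma adjusted p = 0.0195). With each of the 7 libraries left out in turn, Rpl38-ps2 lost its call as deposited in 6 fits (log2 -2.45, and -1.08 without HU 1) and Rpl15-ps3 in 4 (-4.91, and -2.52 without HU 1), as Rpl15-ps3 did in Gem.

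In HU, 5541 genes passed, 619 higher and 4922 lower, and after scaling 1403 passed, 650 higher and 753 lower, with 1285 called in both. Of the 40 genes that the rule took and that passed, 29 also passed after scaling and 12 after the length and level correction. The count was 3035 without HU 1 and 3651 without HU 2.

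Ribosomal protein and oxidative phosphorylation genes were lower nearly throughout in HU. Of 80 genes 78 fell (78 adjusted over the list alone), and 50 fell after scaling (68 adjusted over the list alone), with a relative median of -0.62 (limma camera, Benjamini-Hochberg adjusted p = 4.86e-16, and 0.653 with an estimated correlation). Rpl7a fell to 311 ± 17.4 FPKM and Rpl29 to 284 ± 9.49. Of 48 oxidative phosphorylation genes 47 fell (48 adjusted over the list alone), and 29 after scaling (34 adjusted over the list alone), with a relative median of -0.46 (camera adjusted p = 1.35e-13, and 0.653 with an estimated correlation). Cox5b fell to 257 ± 8.64 FPKM, Ndufb3 from 126 ± 8.90 to 60.3 ± 6.70 and Ndufb5 from 155 ± 8.16 to 84.6 ± 1.58. In both lists the relative median of each HU library, at most -0.50 and -0.46, lay below those of all 3 DMSO libraries. With the length and level correction the relative medians in HU were -0.29 for ribosomal proteins (camera adjusted p = 1.825e-15) and -0.080 for oxidative phosphorylation (0.0199).

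The remaining lists that passed in HU followed those of Gem in part. In the list of DEK and histone chaperones 21 of 24 genes fell (23 adjusted over the list alone) and 5 after scaling (5 adjusted over the list alone), among them Set, Cbx3 and Asf1a (camera adjusted p = 1.80e-05, and 0.653 with an estimated correlation). Of 42 DNA replication genes 31 fell (33 adjusted over the list alone) and 4 after scaling (8 adjusted over the list alone), Rpa3, Orc6 and Gmnn among them (adjusted p = 8.29e-04, and 0.659 with an estimated correlation). Of 35 ribosome biogenesis genes 29 fell (32 adjusted over the list alone) with Npm1, Fbl and Nop56 in front and 2 after scaling (2 adjusted over the list alone; camera adjusted p = 1.73e-04 as deposited, and 0.653 with an estimated correlation). Of 33 nucleotide metabolism genes 26 fell (27 adjusted over the list alone) and 3 after scaling (3 adjusted over the list alone; adjusted p = 8.29e-04 as deposited, and 0.653 with an estimated correlation). Of 46 G2/M genes 31 fell (32 adjusted over the list alone) and 1 after scaling (1 adjusted over the list alone; adjusted p = 0.00124 as deposited, and 0.659 with an estimated correlation), including Birc5, Smc4 and Pttg1. In the integrated stress list 24 of 35 fell (27 adjusted over the list alone) and 2 after scaling (2 adjusted over the list alone; adjusted p = 0.00202 as deposited, and 0.653 with an estimated correlation), with the stress factors Atf4 and Ddit3 at log2 fold changes of -0.78 and -0.92 and Sdf2l1 at -0.59. These 6 lists passed after scaling too. With the length and level correction 0 of the 6 passed. The camera adjusted p was then 0.0513 for DEK and histone chaperones, 0.586 for DNA replication, 0.105 for ribosome biogenesis, 0.126 for nucleotide metabolism, 0.194 for G2/M and 0.675, tested as higher, for the integrated stress list.

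Lysosome and autophagy genes were lower in HU as deposited, 23 of 35 (23 adjusted over the list alone), with Cd63, Gabarapl1 and Gabarap at -0.57, -0.56 and -0.57. The call (camera adjusted p = 0.0290, and 0.653 with an estimated correlation) was lost without DMSO 3 (0.0637) or HU 1 (0.0838), and after scaling 0 genes passed in limma and camera's direction turned to higher (adjusted p = 0.781). The list passed as higher in HU with quantile normalization (relative median 0.21, camera adjusted p = 4.52e-05) and with the length and level correction (0.16, adjusted p = 2.61e-04). The direction called depended on the scale. The immediate early list passed as higher (camera adjusted p = 0.0290, 0.104 after scaling, 0.121 without HU 2, and 0.653 with an estimated correlation) with 4 of 20 genes higher and 5 lower (4 and 7 adjusted over the list alone) and a median of -0.23. After scaling 4 further lists passed as lower: mast cell and basophil markers (adjusted p = 7.82e-04), mitochondrially encoded genes (0.00729), megakaryocyte and platelet markers (0.0268) and replication-dependent histones (0.0285). As deposited these had adjusted p of 0.123, 0.0578, 0.0849 and 0.998. The mean of the mitochondrially encoded list was 0.40 relative to all genes, against a median of -0.31 and a test as lower, and the list holds mt-Tq. With the length and level correction mast cell and basophil markers passed as lower (-0.66, adjusted p = 0.00111) and the oxidative stress response as higher (0.20, adjusted p = 0.001005). As deposited 4922 of all 13865 genes tested fell in HU, beside which the member counts of lists stand. The 20 lists that did not pass had camera adjusted p from 0.0578 to 0.998. Among them were p53 targets (0 of 34 higher and 9 lower, 3 adjusted over the list alone; adjusted p = 0.787), the Fanconi anaemia pathway (9 of 26 lower, 9 adjusted over the list alone; 0.998), the replication checkpoint (1 of 30 higher and 13 lower, 1 and 13 adjusted over the list alone; 0.859) and stem cell identity (12 of 37 lower, 11 adjusted over the list alone; 0.769). The test, median and mean also differed in sign for p53 targets, the Fanconi, oxidative stress and histone lists. With an estimated correlation 0 lists passed in camera, 1 at an unadjusted p under 0.05, while fry called 29.

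**Figure D3:**
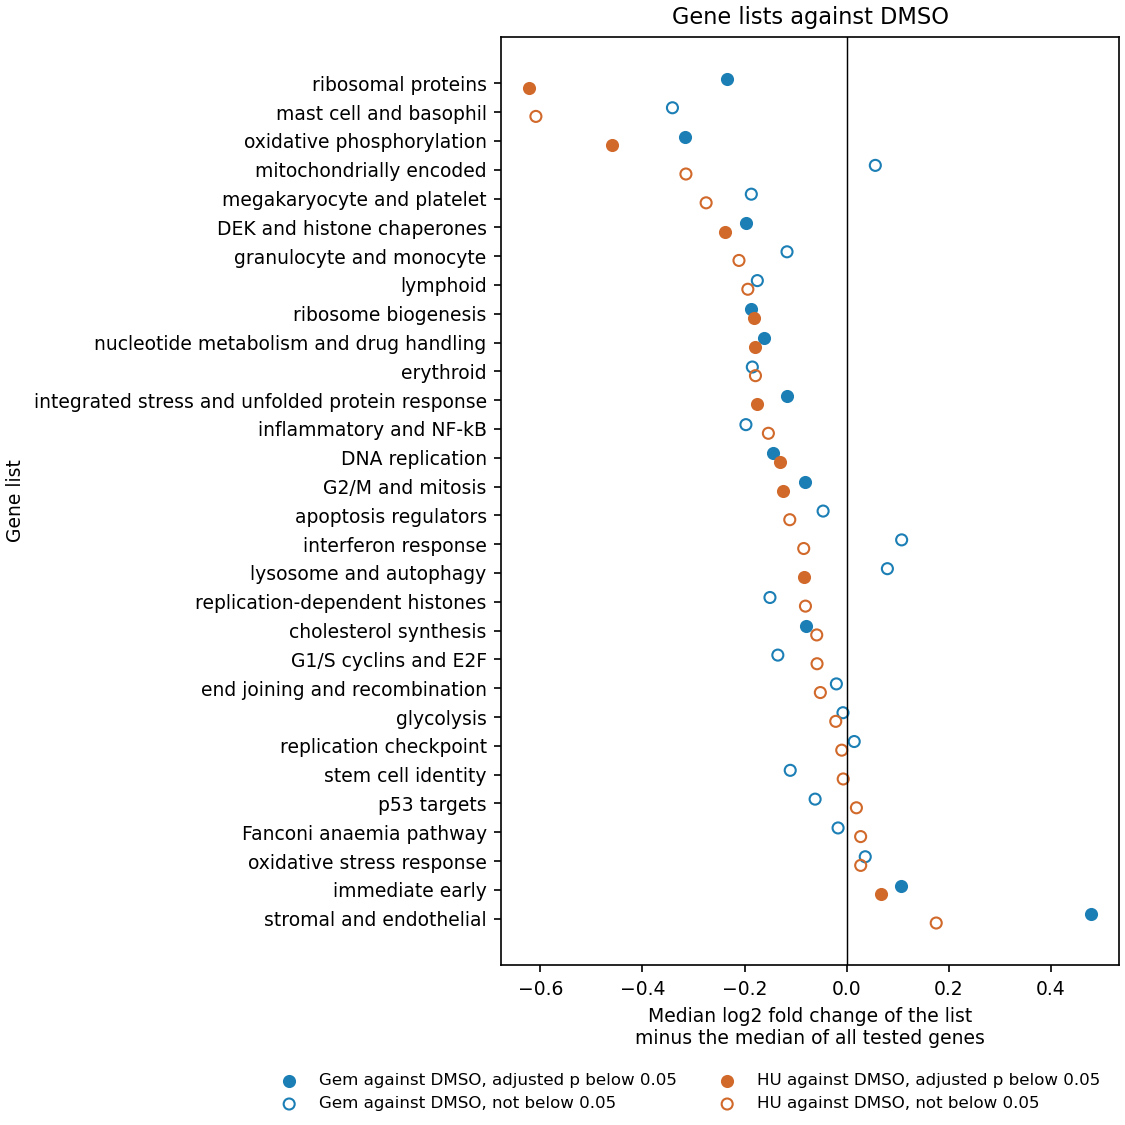
The horizontal axis is the median log2 fold change of a gene list minus that of all tested genes, for Gem against DMSO and HU against DMSO; each line is 1 of the 30 lists, and filled points have a camera adjusted p below 0.05. Oxidative phosphorylation lies at -0.32 and -0.46 and ribosomal proteins at -0.24 and -0.62.

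Gem against HU, the test of whether the drugs differed, called few genes. In limma 3 genes were higher and 11 lower in Gem, and 1484 had an unadjusted p under 0.05; after scaling 3 were higher and 15 lower. Most calls were short RNAs and pseudogenes listed at 0 in both Gem and DMSO. They were above 0 only in HU, so these calls do not show a loss in Gem. Named among the higher genes were Mir1982 and the pseudogene Rps27a-ps2, at 48.4 ± 0.849 FPKM in Gem and 20.1 ± 0.339 in HU (limma adjusted p = 0.0281, but at least 0.0812 without DMSO 1, Gem 1, Gem 2, HU 1 or HU 2). Usp2, Smim4, Hba-a2, Brms1l and Kdm5c did not pass (adjusted p from 0.0883 to 0.255). Usp2 passed with no trend (0.0315). Lbhd1, at 4.49 ± 1.15 in Gem and 17.3 ± 0.276 in HU, passed after scaling (limma adjusted p = 0.0348, 0.0522 as deposited and 0.0389 without DMSO 2). The difference of Jun was -0.084 (log2, 95% interval -0.43 to 0.26), that of Fos -0.080 (-0.29 to 0.13) and that of Dek 0.12 (-0.052 to 0.29), intervals not adjusted for the number of genes. The 14 calls were 5 without DMSO 1, 9 without DMSO 3, 2 without Gem 1, 4 without Gem 2 and 3 without HU 2.

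Of the 30 lists 5 passed as higher in Gem than in HU. Ribosomal protein genes led, with a relative median of 0.39 (limma camera adjusted p = 3.14e-30, and 0.884 with an estimated correlation, as for each of the 5); 53 of 80 passed when adjusted over the list alone and 0 over all genes tested. Oxidative phosphorylation (0.14, adjusted p = 1.35e-08), mitochondrially encoded genes (0.32, adjusted p = 1.42e-04, mean -0.082) and lysosome and autophagy genes (0.073, adjusted p = 0.00124, and 0.018 with adjusted p = 0.0515 without Gem 2) followed, with 0, 6 and 0 genes adjusted over the list alone. The list of DEK and histone chaperones (0.088, adjusted p = 0.0394, 0 genes adjusted over the list alone) was lost after scaling (0.135) and without DMSO 1 (0.0505), Gem 1 (0.317, relative median 0.017), HU 1 (0.0646) or HU 2 (0.212), and without DMSO 3 the lists numbered 8. Mast cell and basophil markers passed after scaling (adjusted p = 0.0323). With an estimated correlation 0 lists passed in camera, 1 at an unadjusted p under 0.05, and fry called 0. With the length and level correction only ribosomal proteins kept their call (relative median 0.23, adjusted p = 1.04e-17), and the adjusted p was 0.703 for oxidative phosphorylation, 0.455 for mitochondrially encoded genes, 0.649 for DEK and histone chaperones and 0.893, tested as lower, for lysosome and autophagy genes. The other 25 lists had camera adjusted p from 0.0781 to 0.907.

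Both drugs pooled against DMSO asks what differed between the drug and the DMSO libraries, as replication stress itself was not measured. Limma called 5614 genes over 4 drug and 3 DMSO libraries, 413 higher and 5201 lower, and after scaling 844, 325 higher and 519 lower. Across the 13865 genes, which are not independent replicates, the fold changes of Gem and HU had a Pearson correlation of 0.724 and a covariance of 0.183. Unchanged groups simulated against the same DMSO libraries gave 0.400 and 0.0405, so the covariances differed by 0.142. After scaling the correlation was 0.661, and 74.1% of genes had the same sign, against 63.2% in the simulations. After scaling 57 genes were called higher in both drugs and 57 lower in both, where independent lists would share 3.14 and 3.53 and the simulations at most 1 and 0. As deposited 153 were higher and 2932 lower in both, against 9.29 and 1141 for independent lists. Simulated unchanged groups have few genes to call, so their low shared counts were fixed in advance and are no yardstick for these lists. Independent lists ignore the shared DMSO libraries. The 3 DMSO libraries cannot be split into parts of at least 2 each, so part of the excess over independent lists may come from the shared controls.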

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

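The length correction, the length and level correction and trimmed-mean scaling of the list tests were chosen after the data were seen; the other alternatives were planned. The rises of Jun, Fos, Nfkb2 and Egr1 passed under every scaling and both corrections in both drugs, as did the falls of Cbx3, Set and Rpa3. In Gem the log2 fold changes of Nfkb2, Egr1, Cbx3, Set and Rpa3 were 2.27, 1.87, -2.06, -1.04 and -1.02 as deposited. Without Gem 2 they were 2.24, 1.64, -2.27, -0.92 and -0.96. These 5 calls were lost in that fit, which has 1 Gem library left, although the changes kept their sign. In the comparisons with DMSO the numbers of genes called lower did not hold under any rescaling. Sequencing depth is unknown, so what it limits cannot be told. Where a library was left out of a pair, the lone one was assumed to vary like the other groups. For each value below that did not hold, the cause was not tested, except that rescaling removes the shift of the median gene by construction.

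For Gem against DMSO the 3421 genes became 1509 with no filter, 3848 at a mean FPKM of at least 5 (59 higher, from 208), 440 on the TPM scale, 67 with quantile normalization, 132 with trimmed-mean scaling, 2132 with no trend, 322 with the length correction, 55 with the length and level correction, and 12 to 3367 with 1 library left out. For HU against DMSO the 5541 genes, 619 higher and 4922 lower, became 7161 with no filter (3279 higher and 3882 lower), 5069 at a mean FPKM of at least 5 (69 higher and 5000 lower), 1478 (TPM scale), 560 (quantile), 1403 (trimmed mean), 1793 (length), 213 (length and level) and 3035 to 5192 (1 library out). For both drugs pooled the 5614 became 3945 with no filter, 5332 at a mean FPKM of at least 5 (72 higher, from 413), 1371 (TPM scale), 383 (quantile), 844 (trimmed mean), 1277 (length), 221 (length and level), and 3774 to 5481 with 1 library left out. For Gem against HU the 14 became 1 with a pseudocount of 0.1, 2 with no filter, 2 at a mean FPKM of at least 5, 64 with no trend, 4 with the length correction, 1 with the length and level correction and 2 to 18 with 1 library left out.

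The lists passing in Gem, HU and Gem against HU were 5, 6 and 2 with quantile normalization, 6, 5 and 1 with the length and level correction, 0, 0 and 0 with an estimated correlation, and 23, 29 and 0 with fry; with 1 library left out they ranged over 9 to 12, 9 to 13 and 4 to 8. The correlation of the fold changes was 0.617 with quantile normalization and 0.625 to 0.751 with 1 library left out.

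With quantile normalization log2 fold changes turned to 0.022 for Mdm2, 0.067 for Rrm2 and 0.13 for Spp1 in Gem, and to 0.25 for Mdm2, 0.18 for Rrm2, 0.076 for Mki67 and 0.028 for Gabarap in HU. The integrated stress list then tested as higher in HU with a relative median of -0.019, the lysosome list passed as higher at 0.21 (camera adjusted p = 4.52e-05), and the lysosome list of Gem against HU turned to -0.00896. On the TPM scale Mdm2 and Mki67 in HU turned to 0.15 and 0.057. With trimmed-mean scaling Spp1 in Gem turned to 0.046, Mdm2, Rrm2 and Mki67 in HU to 0.17, 0.016 and 0.073, and the lysosome list in HU tested as higher at -0.036. With the length correction Spp1 in Gem was at 0.034 and Mdm2 in HU at 0.076. With the length and level correction Rrm2 and Spp1 in Gem were at 0.082 and 0.24, Mdm2, Rrm2, Sdf2l1, Gabarapl1 and Gabarap in HU at 0.20, 0.18, 0.15, 0.029 and 0.058, the integrated stress and lysosome lists in HU at 0.026 and 0.16 (the second passing as higher, camera adjusted p = 2.61e-04), and the lysosome list of Gem against HU at -0.0047. With 1 library left out Sparc ranged from -0.38 to 1.70, Cxcl12 from -0.13 to 0.70 and Spp1 from -0.64 to 0.14 in Gem.

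No pairing by replicate number was seen: deviations of libraries with the same number correlated at 0.01 to 0.05 between DMSO and a drug and at -0.07 between Gem and HU. The 2 libraries of a drug deviate as mirror images, so the Gem and HU pairs give a single value. Low correlations cannot exclude that libraries were handled in pairs. With the replicate block 2877 genes passed in Gem, 4835 in HU, 4337 in both pooled and 2 in Gem against HU, and 12, 13 and 8 lists.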

Other observations

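Genes named here outside the rule, the set of olfactory and vomeronasal genes and their detection count, and the tests of a shared scale factor, of the other immediate early genes and of the shift of the median gene were chosen after the results were seen, as was the 2 SD requirement described with the list falls.

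Mast cell and basophil markers had a list median of -0.64 in HU after scaling. Besides Fcer1a, Mcpt8, a basophil protease gene, was at 166 ± 135 FPKM in DMSO (SD, n = 3) and 40.7 ± 4.85 in HU (n = 2, limma adjusted p = 0.0793), and Cd200r3 at 11.5 ± 6.66 and 2.66 ± 0.863 (limma adjusted p = 0.0334, but 0.129 after scaling). Some early response genes were lower where Jun was higher. In Gem Junb was at 29.6 ± 0.665 FPKM against 47.0 ± 1.41 in DMSO (limma adjusted p = 0.00575, but 0.0832 after scaling), and Nfkbia, the inhibitor of NF-kB, at 113 ± 0.205 against 186 ± 20.7 (limma adjusted p = 0.0236, but 0.283 after scaling). Atg13, an autophagy gene, rose from 20.3 ± 1.24 FPKM in DMSO to 36.3 ± 1.03 in Gem and 43.0 ± 4.89 in HU, and passed after scaling in both (limma adjusted p = 0.0102 and 0.00249). S100a4, a calcium-binding protein gene, fell in both on both scales, with scaled log2 fold changes of -0.998 and -0.833 (limma adjusted p = 0.0102 and 0.00758).

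Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, called as many genes: 5614 as deposited against 26 in the highest other split, and 1 of 35 after scaling, 844 against 25. As 1 of 35 is the smallest share that these splits allow, chance in the grouping is unlikely for both counts but not excluded. Every other split puts drug and DMSO libraries into the same group, which widens its spread. The gap between the counts therefore does not measure how unlikely chance is.

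The drug libraries showed more genes above 0, lower FPKM sums and a lower median gene. Deeper sequencing alone was argued against, since the summed FPKM of olfactory and vomeronasal genes, already divided by depth, was 6.28 times as high in the drug libraries, with no overlap. A candidate explanation is background fragments spread over the genome, such as genomic DNA. The number of olfactory and vomeronasal genes above 0 was 2.91 times as high, against 1.32 for all genes. That comparison cannot decide, since the first set had more room to rise. In DMSO 395 of its 1998 genes were above 0 on average, against 22304 of all 52224. The mean FPKM of the olfactory and vomeronasal genes was also extended over the genome, taking FPKM as divided by all mapped fragments. It gives a background of 4.64% of the fragments in DMSO, 21% in Gem and 37.3% in HU. This predicts shifts of -0.27 and -0.61 beside the observed -0.25 and -0.30. The test bounds (0.5 to 2 times) were set after these values had been estimated, and the HU shift stays open, since it is over-predicted. A change in the cells' own RNA by the drugs stays open too, as the design ties background and drug together.

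The falls of oxidative phosphorylation and ribosomal protein genes might reflect a shared scale factor, a trend with transcript length, or with length and level. Fold changes as deposited were lower at higher mean levels (Spearman's rho -0.452 in Gem and -0.532 in HU, across genes that are not independent replicates). A shift shared by all genes gives such a sign by itself, since log2(FPKM + 1) understates the change of genes with low values. The most abundant genes in DMSO, Ftl1, Lyz2 and Fth1, went the other way. After scaling the oxidative phosphorylation median was -0.26 in Gem and -0.40 in HU, and after the length correction -0.24 and -0.39, which argues against those 2 as the whole cause; the same holds for ribosomal proteins in HU, at -0.56 and -0.55. After the length and level correction the medians were -0.063 and -0.080 for oxidative phosphorylation and -0.081 and -0.29 for ribosomal proteins, within 2 SD of the DMSO libraries, so a trend with level stays open for all 4, and for ribosomal proteins in Gem so do the other explanations (-0.18 and -0.17). Camera still called the list lower in every case, a bound set in advance for the 2 corrections and afterwards for the scaling, but it ignored the spread between DMSO libraries (SD 0.145 for the ribosomal protein median as deposited); non-overlap and then a distance of 2 SD were added after the values were seen. In HU both lists met non-overlap after the length and level correction, so they stay open only by the distance of 2 SD. The HU libraries were then at -0.083 and -0.072 for oxidative phosphorylation, against -0.052 in the lowest DMSO library. For ribosomal proteins they were at -0.20 and -0.39, against -0.16, with a DMSO SD of 0.154. A direct effect of the drugs on these genes was not tested.

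Jun, Fos, Egr1 and Nfkb2 rose by 2.098 to 3.418 (scaled log2) in both drugs. A rise of the immediate early list as a whole was argued against for its members Jun, Fos and Egr1. The other 17 genes of the list had a scaled median of -0.025, and as deposited 1 was called higher and 5 lower in each drug. Nfkb2 is not in that list, so the test does not bear on it. Background fragments were argued against as well, since the 99th percentile of olfactory and vomeronasal genes in the drug libraries was 0.873 FPKM, below the smallest rise of the 4 genes averaged over both drugs, 9.55 for Egr1. The highest of those genes reached 8.78, about the rise of Egr1 in Gem alone (2.27 to 11.0), so this holds less firmly for Egr1 than for the other 3. Reads of the genes that overlap Jun and Nfkb2 on the other strand stay open, as strand is not recorded. A response of a few factors to stalled replication is a hypothesis only. Stalled replication was not measured, and the design could not separate such a response from other differences between the cultures.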
